A study of Mus musculus with 2 samples.

How the data were processed

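Brain tissue of C57BL mice aged 8 to 13 weeks was minced and digested with enzymes at 37°C, per the labels' protocols, and cells were separated into CD45-negative and CD45-positive subsets. How many mice entered each library and how the subsets were separated are not given in the sources used here. Droplet libraries of 3' ends were made with 10x Genomics v3 chemistry, per the labels' protocols. The deposited values are counts of UMIs per gene and cell, made with Cell Ranger 6.1.2 per the file headers, and were not normalised before deposit as far as the values show. The genome build was mm10, per the submitters' processing notes. The annotation release, the cell-calling settings and any removal of doublets before deposit are not given in the sources used here. A 3' assay counts transcripts near their ends, so isoforms were not told apart, and genes with near-identical copies, such as MHC class I, immunoglobulin and haemoglobin genes, may share reads. Gene positions were taken from GENCODE M21, whose build GRCm38 is that of mm10, matched on gene ID.

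The files held 32285 genes. Barcodes were kept with at least 500 UMIs, at least 200 detected genes and at most 20% mitochondrial UMIs. The lowest barcode had 501 UMIs in the CD45-negative and 500 in the CD45-positive library, so the UMI minimum removed nothing. The gene minimum was missed by 52 and 0 barcodes and the mitochondrial limit by 858 and 54. Scrublet, in scanpy 1.11.5, was run on each library with an expected doublet rate of 0.8% per 1000 barcodes, that is 11.6% and 6.93%. It called 876 barcodes (6.03%) and 177 barcodes (2.04%), which were removed. The calls stayed below these assumed rates, so doublets are likely to remain among the kept cells, and their number was not measured. The median mitochondrial share of kept cells was 3.23% in the CD45-negative and 1.59% in the CD45-positive library. Barcodes found in both libraries numbered 27.

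Counts were scaled to 10000 per cell and log-transformed for clustering only. Both libraries were clustered together without integration, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, seed 0). Clusters were named "-like" from 22 marker lists fixed in advance. The markers were fixed in advance, and the numbers of the naming rule below were set after the clusters had been seen. A name needed at least 3 markers detected in at least 20% of the cluster's cells and a positive mean log2 fold over other clusters. A cluster that carried at least 5 markers and a mean log2 fold over 1 of a further class was clustered again at resolution 0.5, which took 29 clusters to 48. A cluster was left unnamed where its leading genes were markers of another class, or where a further class with at least 5 detected markers scored within 0.5 of its own, which held 255 CD45-positive (3.02%) and 6 CD45-negative cells (0.0468%). It was also left unnamed where its median UMI count was under 0.3333 of its library's and none of its own markers was among its 10 leading genes. This held 853 CD45-positive (10.1%) and 13 CD45-negative cells (0.101%) with microglia markers, and 173 CD45-negative (1.35%) and 2 CD45-positive cells (0.0237%) with pericyte markers. Clusters with markers of a further class and a median over 3 times the library's were left unnamed as well, which applied to 24 CD45-positive cells (0.285%).

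Each group has 1 library, so no test between groups was made, no p-value is given and no count of changed genes is made. UMIs were summed per library or per class and expressed as CPM with exact Poisson intervals. Ratios carry exact conditional binomial intervals and shares of cells Clopper-Pearson intervals. A gene with 0 UMIs was set against a floor of 3 UMIs over the library, equal to 0.0363 CPM in the CD45-negative and 0.0406 CPM in the CD45-positive library, or over the class. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs, which left out 684 CD45-negative and 814 CD45-positive cells as too shallow. For the whole libraries a list's median log2 ratio was taken over members with at least 20 UMIs in both libraries together, and its percentile over 10000 random lists of the same size matched on mean expression. Across classes, lists were summed in classes of at least 50 cells, leaving a class's own markers out. In the CD45-negative library the leading class was taken among non-immune classes, with the microglia-like sums given apart, a choice made after seeing the data. Intervals were tested on simulated Poisson counts for the whole libraries with 15469 genes. Such counts follow the model behind the intervals, so the coverage checks the code only and not UMIs clumped in single cells. Medians of 50 genes each set at log2 ratios of 1, -1, 2 and -2 came out at 1.02, -1.00, 2.01 and -2.01, and intervals held the true value for 94.0, 92.0, 94.0 and 94.0% of them. A simulated list raised by 2 came out at 2.01 on the 100th percentile, and an unchanged list at the 10.9th.

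The 25 gene lists, the markers and the rule for named genes were fixed before the data were examined. The lists cover interferon-stimulated genes, chemokines and their receptors, cytokines, complement components and regulators, Fc receptors, MHC class I and II presentation, homeostatic and damage-associated microglia genes, reactive astrocyte and end-foot genes, adhesion molecules, integrins, blood-brain barrier, myelin, neutrophil granule and mature neutrophil genes, early activation, hypoxia and glycolysis, lipid handling, cell cycle, inflammasome and cell death, and haemoglobin genes. Some genes stand in several lists, such as Lcn2, Apoe, Csf1 and Slc2a1, and some are also naming markers. The rule named Ptprc and Aqp4. Between whole libraries it named the 12 genes per direction with the largest ratio by the interval bound nearest to 1, among genes with at least 200 UMIs in the higher library. Within classes held by at least 100 cells of each library it named 12 per direction with at least 50 UMIs and at least 20% of the level in the highest class. Mitochondrial, ribosomal protein, haemoglobin, marker, Gm and Rik genes were left out of these. Of each list it allowed the 4 members with the highest CPM in the leading class or library and any member at least 4-fold apart between libraries, from which examples are printed. It also gave 5 genes that describe each class. Other genes named by class or as exceptions of a list, among them Sele, Selp, C3, Cxcl10, Ccl2, Cxcl5, Ccl5, Gzmb, Ifng and S100a9, were chosen after their values were seen. Results of a few genes, some of them named by the rule, are not reported here.

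The alternatives were no cell filter, a stricter filter (at least 500 genes and at most 10% mitochondrial UMIs), called doublets kept, Leiden resolutions 0.5 and 2, each library clustered alone, and scaling by the median of ratios or by TMM (edgeR 4.0.16, R 4.3.3). Further alternatives were at least 1 or at least 100 UMIs per gene, each cell's CPM averaged in place of summed counts, genes under 20% of their highest class left out within a class, and shares without thinning. Chosen after seeing the data were the comparison within classes of at least 50 cells, no splitting of clusters, naming of high-UMI clusters, unnamed clusters counted by their best class, and leaving out of other classes any cell with at least 0.3% of its UMIs on the 10 microglia markers. Figures were drawn with matplotlib 3.10.9. Unnamed clusters entered the whole-library sums and no class comparison. Reads, splicing and immune receptor sequences were not analysed here.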

Results

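The brain of mice in a model of neuromyelitis optica spectrum disorder was profiled by single-cell RNA sequencing 24 h into the model. In this disease antibodies bind aquaporin-4, the water channel of astrocyte end-feet, and complement and leukocytes damage the tissue. Brain cells of C57BL mice were separated by CD45, the surface protein that marks leukocytes, into a CD45-negative and a CD45-positive subset. Each subset gave 1 library, so the 2 groups hold 1 library each and the differences between them have no replicate check. No untreated or control library was analysed here, so every value describes the state of dissociated cells at 24 h and not a response to the model.

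The CD45-negative library held 14524 barcodes with 92691820 UMIs (unique molecular identifiers, each standing for 1 captured transcript molecule). The CD45-positive library held 8662 barcodes with 76182401 UMIs. After filtering, 12817 CD45-negative cells (88.2%) and 8432 CD45-positive cells (97.3%) were kept. The median kept cell had 5412 UMIs and 2259 detected genes in the CD45-negative library, and 6088.5 UMIs and 2088 genes in the CD45-positive library. With every cell thinned to 1000 UMIs the medians were 630 and 621 genes. Levels are UMIs summed over the cells of a library or class, scaled to the total UMIs of that library or class and given as CPM, with exact Poisson intervals. Shares of cells carry exact Clopper-Pearson intervals. All intervals are 95% intervals that cover counting error only, and neither the spread between animals nor that between preparations.

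The gate and the antigen of the disease were examined before any other comparison. Ptprc (ENSMUSG00000026395; mm10 chromosome 1, 138062861 to 138175708, minus strand, protein coding) encodes CD45. Its level was 612 CPM (606 to 618) in the CD45-positive library and 7.90 CPM (7.30 to 8.53) in the CD45-negative library. The difference was 77.5-fold (71.7 to 83.9), or 6.28 on the log2 scale. A Ptprc UMI was found in 85.8% of CD45-positive cells (85.0 to 86.5) and in 1.09% of CD45-negative cells (0.920 to 1.29). After thinning to 1000 UMIs these shares were 47.5% and 0.511%. Endothelial-like cells of the CD45-negative library, which should lack the transcript, had a Ptprc UMI in 0.0700% of cells, or 0.0784% after thinning, at a median of 4455 UMIs. Since the cells were chosen on this protein, its transcript checks the labels and is no finding.

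Aqp4 (ENSMUSG00000024411; mm10 chromosome 18, 15389496 to 15410982, minus strand, protein coding) encodes aquaporin-4. It was 85.0-fold (74.6 to 97.2) higher in the CD45-negative library, at 264 CPM (261 to 268) against 3.11 CPM (2.72 to 3.54). Astrocyte-like cells of the CD45-negative library carried Aqp4 at 714 CPM (704 to 724). An Aqp4 UMI was found in 81.5% of these cells, and in 46.1% after thinning, at a median of 5234 UMIs per cell. Neuroblast-like cells, which should lack the gene, had an Aqp4 UMI in 8.40% of cells, or 1.34% after thinning, at a median of 7818.5 UMIs. Aqp4 was at 22.98 CPM in endothelial-like and 16.1 CPM in oligodendrocyte-like cells. The 69 astrocyte-like cells that passed into the CD45-positive library held 640 CPM (553 to 737).

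The cell classes on each side of the gate were compared next, with every cluster named from markers of 22 cell types fixed in advance. Astrocyte-like cells made up 40.8% (39.9 to 41.6) of the CD45-negative library and oligodendrocyte-like cells 21.8% (21.1 to 22.5). Endothelial-like cells followed with 11.1% (10.6 to 11.7), pericyte-like cells with 10.0% (9.53 to 10.6) and neuroblast-like cells with 8.18% (7.71 to 8.66). Choroid plexus epithelial-like cells made up 1.72%, neuron-like cells 1.47%, smooth muscle-like cells 0.780%, fibroblast-like cells 0.694% and ependymal-like cells 0.351%. The neuron-like share rested on 160 low-UMI cells close to the neuroblast markers, and was 0.234% without a cell filter and at Leiden resolutions 0.5 and 2, and 0.220% with doublets kept. No cell was named smooth muscle-like at resolution 0.5 or with no cluster split. Immune classes together held 147 cells, or 1.15% (0.970 to 1.35), of which 85 were microglia-like, 24 neutrophil-like, 21 T cell-like, 16 monocyte-like and 1 NK cell-like. The microglia-like share of 0.663% was 0.328% at resolution 2 and 1.34% with each library clustered alone.

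The CD45-positive library held 36.0% (34.9 to 37.0) microglia-like and 30.9% (29.9 to 31.9) T cell-like cells. Of the microglia-like cells, 979 lay in a cluster with a mean log2 fold of only 0.47 for microglia markers. It had no microglia marker among its leading genes and a Ptprc UMI in 59.7% of these cells, so its name is uncertain. Cells named from monocyte markers, which include monocyte-derived cells and are called monocyte-like here, made up 10.6% (9.98 to 11.3). NK cell-like cells were 3.04% (2.68 to 3.42), neutrophil-like cells 1.53% (1.28 to 1.82) and dendritic cell-like cells 0.700% (0.533 to 0.902). Several of these shares depended on the clustering. The microglia-like share fell with each library clustered alone, where a cluster of 785 cells led by Saa3 was left unnamed. Monocyte-like cells were 5.41% at Leiden resolution 2, 4.54% with each library clustered alone and 5.94% with the stricter cell filter, and dendritic cell-like cells were 3.88%, 3.45% and 2.17% there and absent at resolution 0.5. Neutrophil-like cells were 3.04% with the stricter filter, 4.92% with each library alone and 4.84% with no cluster split, and the 0.818% of astrocyte-like cells was 1.64% with each library alone. With no cluster split the neutrophil-like name took in the unnamed cells with neutrophil and microglia markers together. With each library alone it covered clusters of 179 and 96 cells with 10 detected microglia markers, at medians of 25715 and 19588.5 UMIs. Clusters of 112 and 124 neutrophil-like cells under the stricter filter also had 10 detected microglia markers. All immune classes together came to 82.7% (81.9 to 83.5) and all non-immune classes to 1.76% (1.49 to 2.06). No neuron-like cell was found among the 8432 CD45-positive cells, which allows a share of up to 0.0437%. The CD45 gate and the dissociation set these shares, so they do not measure the makeup of the brain.

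Clusters without a name held 15.5% of CD45-positive and 1.92% of CD45-negative cells. In the CD45-positive library 853 such cells carried microglia markers at a low UMI count, and 279 carried neutrophil and microglia markers together. A further 175 cells, led by Calca, Csf2, Il1rl1 and Gata3, had no class with at least 3 detected markers and a positive mean log2 fold of them. Of the CD45-negative cells without a name, 173 carried pericyte markers at a low UMI count and were led by Il6 and Ccl11, and 54 had Fabp7 among their leading genes. Several named clusters were themselves led by immune or stress genes rather than by their own markers. Among microglia-like cells, a cluster with 979 CD45-positive cells was led by Saa3 and Ccl12, and a cluster with 351 by Tnf, Ccl4 and Atf3. An astrocyte-like cluster of 562 CD45-negative cells was led by Ptx3, Tgm1 and Gfap, and an oligodendrocyte-like cluster of 699 cells by Srxn1 and included Il33 among its leading genes.

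**Figure D1:**
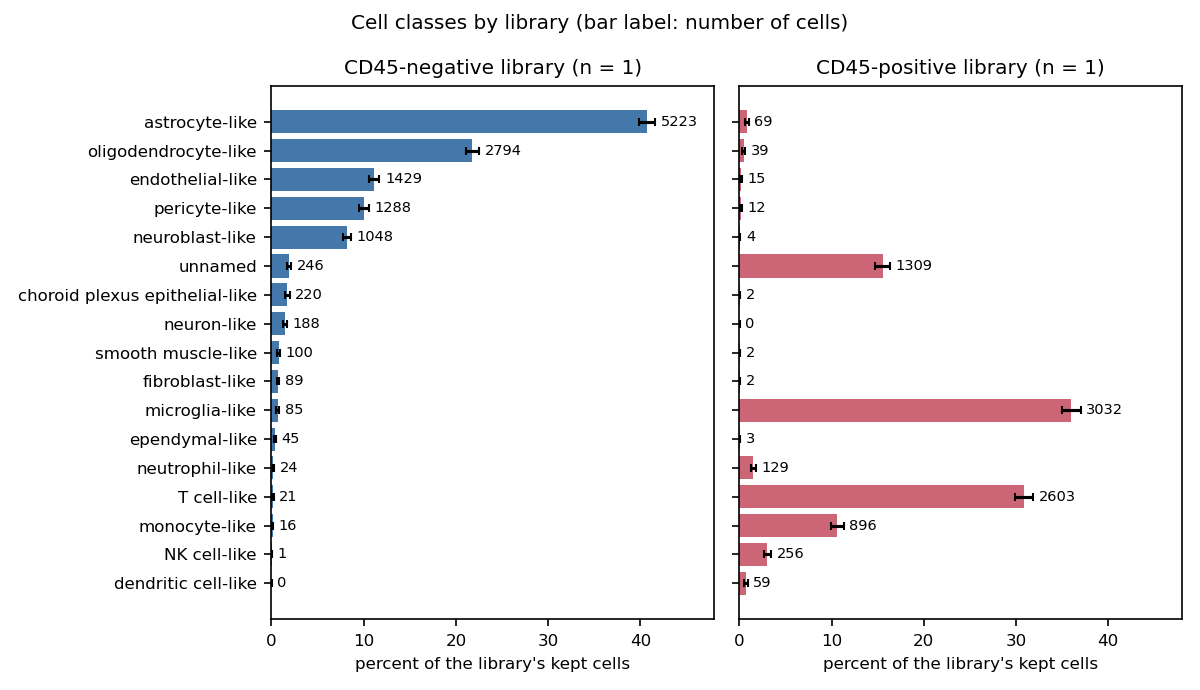
Percent of kept cells in each class (horizontal axis), by class and library, with bars that start at 0, 95% Clopper-Pearson intervals as error bars and cell counts beside the bars. Astrocyte-like cells are the largest CD45-negative class at 40.8% and microglia-like cells the largest CD45-positive class at 36.0%.

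Which gene groups each side of the gate carried was asked with 25 gene lists in the whole libraries. Genes of antigen presentation, Fc receptors, chemokine receptors and microglia were higher in the CD45-positive library, and genes of astrocyte end-feet, myelin and the blood-brain barrier in the CD45-negative library. The CD45 gate chose the cells, so it sets the side of lists of leukocyte, microglia, glial and vascular genes. Random lists were matched on mean expression and not on cell type, so percentiles of such lists describe the gate and lend no support. The median log2 ratio of CD45-positive over CD45-negative CPM was 7.36 for MHC class II presentation, 5.93 for chemokine receptors and 5.36 for Fc receptors. It was -6.45 for aquaporin-4 and astrocyte end-foot genes, -6.22 for myelin genes and -3.08 for blood-brain barrier genes. The median of all 18379 genes with at least 20 UMIs was -0.58, and the list medians are read relative to it. The log2 scaling factor between the libraries was -0.32 by the median of ratios and -0.47 by TMM, which put the median of all genes at -0.26 and -0.10, and no list median changed sign under either. Sides of single members are given by CPM, and under TMM the members Oasl2, Usp18, Ifit1, Stat2, Lif, Cd9, Cd63, Fth1, Lrg1, Slc7a5, Klf2, Aldoa and Mlkl turn from the CD45-negative to the CD45-positive side.

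Antigen presentation and antibody sensing were carried by the CD45-positive library. All 10 MHC class II genes were higher there, among them H2-Aa at 545 against 1.83 CPM (298-fold; ENSMUSG00000036594, mm10 chromosome 17, 34282744 to 34287823, minus strand) and Cd74, the invariant chain, at 1378 against 9.17 CPM. The 13 MHC class I genes were also all higher, with a median of 1.61 and B2m, the light chain, at 1906 against 394 CPM. All 9 measured Fc receptor genes, whose products bind antibody tails or signal for such receptors, were higher, with Fcgr3 at 614 against 14.98 CPM (log2 5.36). The leukocyte integrins and selectin ligands had a median of 5.64, and Itgal was at 69.1 against 0.824 CPM and Itgb2 at 231 against 4.57 CPM. The inflammasome and cell death list had a median of 3.37, with Pycard, the inflammasome adaptor, at 657 against 19.3 CPM, and with Fas, a death receptor gene, at 9.25 against 27.1 CPM as an exception.

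Chemokine, cytokine and complement genes were divided between the subsets. Of the 21 chemokines, 15 were higher in the CD45-positive library and 6 in the CD45-negative library, with a median of 2.40. Ccl12, a monocyte attractant, was at 3161 against 55.4 CPM and Ccl5, a T cell attractant, at 1273 against 39.5 CPM. Cxcl12, which holds leukocytes at vessels, was at 2.43 against 163 CPM, or 67.1-fold higher in the CD45-negative library, as were Ccl11 (162-fold), Cxcl5 (63.6-fold), Ccl19 (58.2-fold), Cx3cl1 (27.2-fold) and Cxcl1 (4.27-fold). Of 20 measured cytokines 12 were higher in the CD45-positive library, with a median of 3.12 and Il1b at 267 against 25.4 CPM. The 8 cytokines on the CD45-negative side included Il33, an alarmin, at 648 against 5.35 CPM (121-fold), Il34, a ligand of the Csf1 receptor, at 36.0 against 0.284 CPM (127-fold), and Il6 at 11.5 against 2.49 CPM (4.63-fold). Of 12 chemokine receptors 10 were higher in the CD45-positive library, among them Ccr2 at 131 against 1.18 CPM, and the scavenging receptors Ackr1 and Ackr3 were 35.4-fold and 19.5-fold higher in the CD45-negative library.

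Complement components had a median of 2.06, with 11 of 17 measured genes higher in the CD45-positive library. C1qa, a chain of the initiating C1q complex, was at 5443 against 100.4 CPM (54.2-fold). The CD45-negative library was higher for Clu, an inhibitor of the terminal pathway, at 1407 against 19.8 CPM (71.2-fold), for C4b at 177 against 15.9 CPM (11.2-fold), and for C1s1, C1ra, C2 and the C1 inhibitor gene Serping1. The complement regulators on cells had a median of -2.14, at the 17.6th percentile of random lists. Cd59a, which blocks the membrane attack complex, was at 38.9 against 0.906 CPM (43.0-fold higher in the CD45-negative library). Cr1l, a C3 regulator, was at 93.6 CPM in the CD45-positive and 63.4 CPM in the CD45-negative library.

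The medians of the glial and vascular lists lay on the CD45-negative side. All 10 myelin genes were higher there, with Mbp at 1050 against 47.4 CPM. Of 12 end-foot genes 11 were higher, among them Glul, the glutamine synthetase gene, at 1331 against 215 CPM. All 14 blood-brain barrier genes were higher, with Slc2a1, the glucose transporter, at 351 against 38.2 CPM. The reactive astrocyte list had a median of -2.87, with 19 of 26 genes higher in the CD45-negative library, such as Gfap at 184 against 4.45 CPM, Serpina3n at 404 against 3.26 CPM and Lcn2 at 229 against 71.2 CPM. Its summed level was nearly equal, at 2222 CPM in the CD45-negative and 2229 CPM in the CD45-positive library. Leukocyte adhesion molecules had a median of -1.95, with 12 of 14 genes on the CD45-negative side, Vcam1 at 88.6 against 10.6 CPM and the exception of Icam1 at 14.8 against 82.7 CPM. Lipid handling genes had a median of -1.68, with Apoe at 5117 against 639 CPM, and the 4 haemoglobin genes a median of -3.27 at the 24.3rd percentile.

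The remaining lists had medians between 0.16 and 5.81. Homeostatic microglia genes had a median of 5.81, with all 14 higher in the CD45-positive library and Tmem119 at 479 against 8.33 CPM. The damage-associated microglia list had a median of 1.41, with 12 of 19 genes higher, and its 7 exceptions included Apoe, Csf1 and Axl. Mature neutrophil genes had a median of 2.54 and neutrophil granule genes of 2.06, with S100a9, a neutrophil marker outside both lists, at 261 against 89.8 CPM. Early activation genes had a median of 1.42, with 19 of 20 higher in the CD45-positive library and Fos at 263 against 74.5 CPM. Hypoxia and glycolysis genes had a median of 0.52, with Ldha at 413 against 136 CPM and Vegfa at 10.5 against 132 CPM. Cell cycle genes had a median of 0.33, with Mki67 at 22.8 against 18.3 CPM. Interferon-stimulated genes had a median of 0.16, at the 89.5th percentile, with 12 genes higher in the CD45-positive library, such as Ifi27l2a at 861 against 211 CPM, and 9 in the CD45-negative library, such as Ifit3 at 91.7 against 140.0 CPM. The percentile among 10000 matched random lists was 92.6 for hypoxia and glycolysis, 98.2 for cell cycle, at least 99.7 for each other list with a positive median, and at most 2.27 for the other lists with a negative median. Sums ran against positive medians for cytokines (789 against 961 CPM), damage-associated microglia genes (15814 against 17371 CPM), cell cycle genes (970.2 against 1387 CPM) and neutrophil granule genes (209.8 against 238 CPM). All of these but cell cycle genes differed by less than either scaling factor and turn to the CD45-positive side under both.

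**Figure D2:**
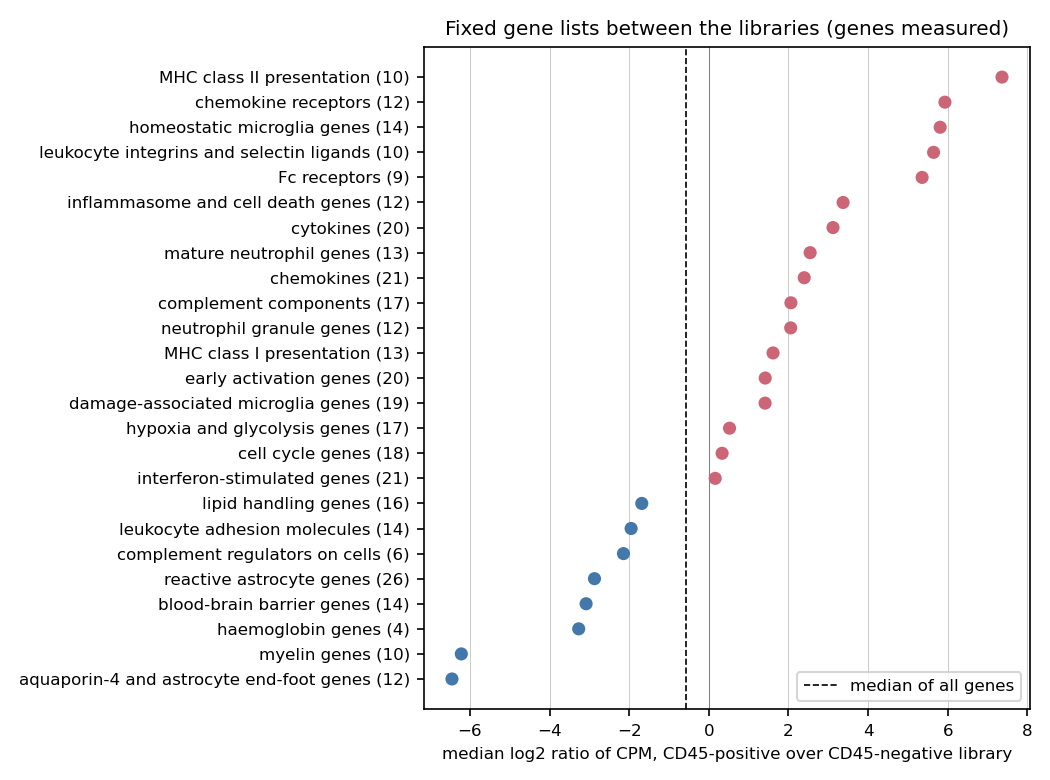
Median log2 ratio of CD45-positive over CD45-negative CPM (horizontal axis) for each of the 25 gene lists (dots), with a dashed line at the median of all genes, -0.58. MHC class II presentation lies farthest right at 7.36, and aquaporin-4 and astrocyte end-foot genes lie farthest left at -6.45.

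The genes named by size between the whole libraries mostly marked single classes or a few cells. On the CD45-positive side H2-Aa, H2-Eb1 (log2 7.77, 7.56 to 7.99) and H2-DMb2 (862 UMIs against 0, at least 321-fold higher against a floor of 3 UMIs) lay mainly in the cluster named monocyte-like, with 86.7%, 85.0% and 74.6% of their UMIs. That cluster was itself led by H2-Ab1, H2-Aa, Cd74 and H2-Eb1. At Leiden resolution 2 the name was left to 456 cells led by Arg1 and Chil3, and H2-Aa was among the leading genes of dendritic cell-like clusters of 145, 83 and 37 cells. Clusters of 53 plasmacytoid dendritic cell-like and 30 B cell-like cells were also found there. NK cell-like cells held 87.8% of Gzmc, a granzyme, 62.3% of Xcl1, a chemokine, and 48.1% of Klrb1b. Gzmc had 1026 UMIs against 1 (log2 10.16, 7.68 to 15.47) and Xcl1 had 2098 UMIs against 4 (log2 9.19). Calca (203 against 0.690 CPM) and Csf2, which encodes the growth factor GM-CSF (730 UMIs against 0, at least 272-fold higher against the same floor), came from the unnamed cluster of 175 cells, with 92.0% and 89.0% of their UMIs. The immunoglobulin gene Igkc (356 against 0.388 CPM) rested on 3 cells with 92.3% of its UMIs, and Igha and Ighg2b each on 1 cell with 92.1% and 96.3%. A single T cell-like cell held 92.4% of the 606 Il13 UMIs, and Il13 had 0 UMIs in the CD45-negative library.

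On the CD45-negative side, neuroblast-like cells held 88.7% of Nxph1, 81.9% of Ube2ql1 and 76.9% of Mir124a-1hg. Nxph1 had 639 UMIs against 0. Choroid plexus epithelial-like cells held 97.3% of Mmp3, a matrix metalloproteinase, at 38.1 against 0.122 CPM, and 89.7% of Ecrg4. Lamb1, a laminin chain (833 UMIs against 0), came mainly from pericyte-like cells with 59.9%, and Nptx2 (751 UMIs against 0) from astrocyte-like cells with 69.6%. Rian, Pak3, Tro and Snhg11 were named as well, and neuron-like cells held 65.0% of Snhg11.

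Which resident class carried each list was compared within the CD45-negative library, across 9 non-immune classes with at least 50 cells. Endothelial-like cells led the chemokine, adhesion, complement regulator, Fc receptor, MHC class I and barrier lists. Astrocyte-like cells led complement components and lipid handling, oligodendrocyte-like cells led cytokines through Il33, and choroid plexus epithelial-like cells led interferon-stimulated genes. A class's own naming markers were left out of its sums, and no test between classes was made because classes of 1 library are not replicates. Of their astrocyte-like levels, 1.87 to 7.58% of Aqp4 and 2.08 to 10.0% of Slc1a2 were found in the other named classes, and 16.5% of Slc1a2 in the 54 unnamed cells. Free RNA and mixed droplets were not told apart as the source, and low levels are read with these shares in mind.

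The 173 unnamed cells with pericyte markers took no part in the ranking. Their sums lay above the leading class for chemokines (9096 CPM), cytokines (2643 CPM), MHC class I presentation (5735 CPM), reactive astrocyte genes (6883 CPM) and mature neutrophil genes (4383 CPM).

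Endothelial-like cells carried chemokines at a summed 1741 CPM against 1279 CPM in fibroblast-like cells, 1.36-fold (1.25 to 1.48). Cxcl12 (mm10 chromosome 6, 117168535 to 117181367, plus strand) made up most of it, at 1646 CPM (1615 to 1678) in endothelial-like and 601 CPM in fibroblast-like cells. A Cxcl12 UMI was found in 69.5% of endothelial-like cells, or 52.9% after thinning, at a median of 4455 UMIs, against 2.14% of astrocyte-like cells, or 0.536% after thinning, at 5234 UMIs. Leukocyte adhesion molecules summed to 1752 CPM, 2.61-fold (2.34 to 2.93) over fibroblast-like cells, with Vwf at 413 CPM (397 to 429), Jam2 at 332 CPM, Icam2 at 257 CPM and Vcam1 at 239 CPM (227 to 251). The endothelial selectin gene Sele was at 33.1 CPM and Selp at 25.1 CPM. Blood-brain barrier genes summed to 9206 CPM, 8.51-fold (8.39 to 8.62) over astrocyte-like cells, with Slc2a1 at 3069.5 CPM (3027 to 3112), the efflux pump gene Abcb1a at 1118 CPM and Slco1c1 at 1019 CPM.

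The complement regulators also stood highest in endothelial-like cells, at 525 CPM against 166 CPM in fibroblast-like cells, 3.15-fold (2.53 to 3.99). Cd59a was at 344 CPM (329 to 358) in endothelial-like, 115 CPM in choroid plexus epithelial-like, 21.3 CPM in oligodendrocyte-like and 2.80 CPM (2.22 to 3.48) in astrocyte-like cells. The ratio of astrocyte-like to endothelial-like Cd59a lay below the range given for Aqp4 and Slc1a2. Cr1l was at 168 CPM in endothelial-like and 66.3 CPM in astrocyte-like cells. MHC class I presentation summed to 4658 CPM in endothelial-like cells, 1.36-fold (1.32 to 1.39) over choroid plexus epithelial-like cells, with B2m at 1290 CPM (1263 to 1318) and H2-D1 at 1202 CPM. Fc receptor genes summed to 327 CPM against 223 CPM in fibroblast-like cells, 1.47-fold, nearly all from Fcgrt, the neonatal Fc receptor, at 317 CPM. The inflammasome and cell death list was 2.11-fold over choroid plexus epithelial-like cells, with Fas at 228 CPM, and early activation genes were 1.60-fold over smooth muscle-like cells, with Klf2 at 1752 CPM and Nfkbia at 1053 CPM.

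The reactive astrocyte list was led by endothelial-like cells at 5749 CPM, with fibroblast-like cells at 5012 CPM and astrocyte-like cells at 1937 CPM (1921 to 1953). The leading members in endothelial-like cells were Hspb1 at 1373 CPM and Lcn2 at 1248 CPM (1221 to 1275), a chaperone and a secreted iron-carrier binding protein that are not restricted to astrocytes. The order of endothelial-like over fibroblast-like cells, 0.20 on the log2 scale, turned to -0.05 when each cell's CPM was averaged. In astrocyte-like cells Gfap, an intermediate filament gene, was at 454 CPM (446 to 462), Serpina3n at 374 CPM and Lcn2 at 206 CPM. Serpina3n was higher in oligodendrocyte-like cells, at 781 CPM. Over the 7 end-foot genes outside the astrocyte markers, astrocyte-like cells held 4133 CPM and fibroblast-like cells 1847 CPM, with Glul at 2068 CPM, Dtna at 624 CPM and Kcnj10, a potassium channel gene, at 323 CPM in astrocyte-like cells.

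Complement components summed to 3938 CPM in astrocyte-like cells, 1.51-fold (1.43 to 1.60) over fibroblast-like cells. Clu accounted for 3613 CPM (3591 to 3635) and C4b for 249 CPM (244 to 255), while C3 was at 1.17 CPM. Oligodendrocyte-like cells held C4b at 251 CPM, and choroid plexus epithelial-like cells held C3 at 162 CPM. Serping1 was at 751 CPM in fibroblast-like cells. Lipid handling genes summed to 13430 CPM in astrocyte-like cells, 3.41-fold (3.26 to 3.57) over fibroblast-like cells, with Apoe at 11983 CPM. Of the cytokine-inducible transcripts in astrocyte-like cells, Cxcl10 was at 136 CPM (132 to 140) and Ccl2 at 44.7 CPM.

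Cytokine genes summed to 2066 CPM in oligodendrocyte-like cells, 2.49-fold (2.25 to 2.75) over fibroblast-like cells. Il33 (mm10 chromosome 19, 29925114 to 29960718, plus strand) was at 1857 CPM (1840 to 1873) there, against 356 CPM in fibroblast-like and 105 CPM in astrocyte-like cells. An Il33 UMI was found in 87.6% of oligodendrocyte-like cells, or 59.3% after thinning, at a median of 8971.5 UMIs, against 23.2% of neuroblast-like cells, or 3.73% after thinning, at 7818.5 UMIs. Csf1, a microglial growth factor, was at 126 CPM and Il18 at 71.3 CPM in oligodendrocyte-like cells. Il34 was at 504 CPM (484 to 525) in pericyte-like and 437 CPM in smooth muscle-like cells. Of the myelin list only Mbp (3089.8 CPM) and Cnp (1987 CPM) lie outside the oligodendrocyte markers, and together they were 13.5-fold (11.7 to 15.7) over fibroblast-like cells. The damage-associated microglia list was led by oligodendrocyte-like cells, 1.47-fold over choroid plexus epithelial-like cells, through the ferritin gene Fth1 at 23263 CPM.

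Among the named classes interferon-stimulated genes stood highest in the 220 choroid plexus epithelial-like cells, at 6986 CPM against 1757 CPM in endothelial-like cells, 3.98-fold (3.88 to 4.07). The 173 unnamed cells with pericyte markers were close to them, at 6374 CPM (6165 to 6588). Ifi27l2a was at 2695 CPM (2629 to 2764), Isg15 at 1060 CPM (1018 to 1103), Ifit3 at 558 CPM and Irf7 at 426 CPM. An Ifi27l2a UMI was found in 89.5% of these cells, or 76.5% after thinning, at a median of 9289 UMIs, against 6.47% of astrocyte-like cells, or 1.57% after thinning, at 5234 UMIs. The same epithelial-like cells led hypoxia and glycolysis genes, 1.53-fold over endothelial-like cells with Gapdh at 3379.8 CPM, and neutrophil granule genes, 1.14-fold over endothelial-like cells through Lcn2 at 1416 CPM (1368 to 1466). They also held the neutrophil attractant Cxcl5 at 177 CPM and Ccl5 at 370 CPM.

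Mural cells, fibroblasts, neural precursors and neuron-like cells carried the other lists. Pericyte-like cells led the mature neutrophil list, 1.94-fold over smooth muscle-like cells, through Ifitm1 at 3016 CPM, an interferon-induced membrane protein gene that is not restricted to neutrophils. Smooth muscle-like cells led chemokine receptors, at 311 CPM against 179 CPM in pericyte-like cells, 1.74-fold (1.43 to 2.11), all of it Ackr3, and integrins, 1.14-fold over pericyte-like cells, through Itgb1 at 1085 CPM. MHC class II genes stayed at 47.9 CPM in fibroblast-like and 26.1 CPM in pericyte-like cells. Neuroblast-like cells led the cell cycle list, 5.72-fold (5.29 to 6.18) over neuron-like cells, with Stmn1 at 4277 CPM, Hmgb2 at 1309 CPM and Top2a at 228 CPM. The homeostatic microglia list, through Mef2c and Bin1, was at 903 CPM in neuron-like and 761 CPM in smooth muscle-like cells, an order of 0.25 on the log2 scale that turned to -0.57 when each cell's CPM was averaged. Haemoglobin genes were at 119 CPM in neuroblast-like and 17.4 CPM in pericyte-like cells, a log2 ratio of 2.77 that turned to -2.57 at Leiden resolution 2.

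The 85 cells named microglia-like in the CD45-negative library exceeded the non-immune classes in several lists. Of these 54 lay in a cluster without microglia markers among its leading genes, at a median of 787.5 UMIs and with a Ptprc UMI in 9.26% of cells, so their name is uncertain. Their sums were 20285 CPM for complement components, 8529 CPM for chemokines, 6532 CPM for Fc receptors, 3977 CPM for MHC class II presentation, 1871 CPM for integrins, 1245 CPM for inflammasome and cell death and 492 CPM for chemokine receptors.

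Which leukocyte class carried each list was compared across the 7 classes of at least 50 cells in the CD45-positive library. The 129 neutrophil-like cells led the chemokine, cytokine, interferon-stimulated, Fc receptor, early activation and reactive astrocyte lists. Microglia-like cells led complement components, and dendritic cell-like cells led both MHC lists. NK cell-like, T cell-like and dendritic cell-like cells carried Ccl5. Microglia transcripts were found in every other class of this library. C1qa stood at 4.07 to 38.8% of its microglia-like level in them, and 36.0% of monocyte-like and 30.2% of neutrophil-like cells had at least 0.3% of their UMIs on the 10 microglia markers. Values without those cells are therefore given where they move a result by over 1.5-fold. Unnamed cells took no part in the ranking, and chemokine receptors summed to 3747 CPM in the 853 low-UMI cells with microglia markers against 2015 CPM in monocyte-like cells, with Cx3cr1, itself a microglia marker, as the first member.

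Neutrophil-like cells carried chemokines at a summed 20266 CPM, 2.43-fold (2.36 to 2.497) over NK cell-like cells. Cxcl2 (mm10 chromosome 5, 90903871 to 90905938, plus strand), which attracts further neutrophils, was at 11250.1 CPM (10952 to 11554), Ccl4 at 4037 CPM (3859 to 4221) and Ccl3 at 1834 CPM. A Cxcl2 UMI was found in 89.9% of neutrophil-like cells, or 83.0% after thinning, at a median of 2886 UMIs, against 9.72% of T cell-like cells, or 2.57% after thinning, at 4762 UMIs. Cytokines summed to 6645 CPM, 3.43-fold (3.19 to 3.69) over dendritic cell-like cells, with Il1b at 3602 CPM (3435 to 3776), its antagonist Il1rn at 1703 CPM, Csf1 at 503 CPM and Tnf at 354 CPM. Interferon-stimulated genes summed to 10901 CPM, 1.41-fold (1.35 to 1.47) over dendritic cell-like cells, with Isg15 at 2519 CPM and Rsad2 at 1805 CPM. Fc receptor genes were 1.35-fold over microglia-like cells, through the signalling adaptors Tyrobp at 4579.9 CPM and Fcer1g at 3588 CPM, whereas Fcgr3 was at 893 CPM in microglia-like and 628 CPM in neutrophil-like cells.

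The neutrophil granule list was 5.06-fold over astrocyte-like cells, with Lcn2 at 1963 CPM and Camp, a late granule gene, at 1082 CPM. The early granule genes Elane and Mpo had 0 UMIs in neutrophil-like cells, which allows up to 6.24 CPM. The mature neutrophil list was 2.29-fold over monocyte-like cells, with Msrb1 at 2275 CPM. Early activation genes were 1.81-fold over monocyte-like cells, with Nfkbia at 2517 CPM and Dusp1 at 2336 CPM. The damage-associated microglia list was 2.73-fold over astrocyte-like cells, through Fth1 at 40953 CPM. The reactive astrocyte list was 2.00-fold over monocyte-like cells, through Srgn at 4018 CPM, a proteoglycan gene of leukocyte granules, and adhesion molecules were 1.46-fold over astrocyte-like cells, through Lrg1 at 329 CPM.

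Microglia-like cells carried complement components at 22357 CPM, 2.34-fold (2.33 to 2.36) over monocyte-like cells. This log2 ratio of 1.23 became 3.11 with microglia-marker-rich cells left out of the other classes, a choice made after seeing the data, 1.71 with each cell's CPM averaged and 0.72 at Leiden resolution 2. C1qa (mm10 chromosome 4, 136895917 to 136898803, minus strand) was at 8335 CPM (8304 to 8365), C1qb at 7633 CPM and C1qc at 4549 CPM. Monocyte-like cells held C1qa at 3232 CPM, or 486 CPM without the microglia-marker-rich cells. Ccl12 was at 5109 CPM (5085 to 5133) in microglia-like cells, Tmem119 at 708 CPM, P2ry12 at 404 CPM, Il1a at 87.0 CPM and Il1b at 54.9 CPM. The inflammasome list differed little between microglia-like and neutrophil-like cells, 1.01-fold (0.935 to 1.09), with Pycard at 857 CPM in microglia-like cells. Over the 6 homeostatic genes outside the microglia markers, microglia-like cells held 4377 CPM and monocyte-like cells 2356 CPM.

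Dendritic cell-like cells carried MHC class II genes at 32217 CPM, 1.66-fold (1.64 to 1.69) over monocyte-like cells. This log2 ratio of 0.73 was 0.26 without microglia-marker-rich cells and 1.96 at Leiden resolution 2. H2-Eb1 was at 6176 CPM (5963 to 6396) and H2-Aa at 5920 CPM in dendritic cell-like cells, and H2-Aa was at 2814 CPM in monocyte-like cells, or 4638 CPM without microglia-marker-rich cells. The dendritic cell-like class was described by Ccl22 at 1457 CPM, Il4i1 at 987 CPM and Ccl17 at 582 CPM. MHC class I genes were 1.27-fold (1.24 to 1.30) over T cell-like cells, a log2 ratio of 0.34 that turned to -0.37 at Leiden resolution 2. Monocyte-like cells were described by Arg1, the arginase gene, at 412 CPM, and held Il1b at 777 CPM, Ccl2 at 815 CPM and Ccr2 at 454 CPM. Their chemokine receptor sum was 1.01-fold (0.951 to 1.08) that of neutrophil-like cells. The hypoxia and glycolysis list was 1.03-fold over microglia-like cells, and that log2 ratio of 0.04 turned to -0.04 with each cell's CPM averaged and to -0.06 without microglia-marker-rich cells.

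Ccl5 (mm10 chromosome 11, 83525778 to 83530518, minus strand) was at 7008 CPM (6859 to 7160) in NK cell-like and 4401 CPM (4365 to 4436) in T cell-like cells. Dendritic cell-like cells held it at 4128 CPM. Gzmb, a granzyme of killer lymphocytes, was at 1424 CPM in NK cell-like and 739 CPM in T cell-like cells. Ifng was at 103 CPM in NK cell-like and 54.0 CPM in T cell-like cells. NK cell-like cells led the integrin list, 1.17-fold (1.13 to 1.21) over microglia-like cells, with Selplg at 652 CPM and Itgal at 281 CPM, and the complement regulator list, 1.17-fold (0.984 to 1.38) over microglia-like cells. T cell-like cells led the cell cycle list, 1.48-fold over microglia-like cells, with Hmgb2 at 777 CPM. The 69 astrocyte-like cells led the end-foot list, 8.54-fold over microglia-like cells, blood-brain barrier genes, 3.76-fold over microglia-like cells, and lipid handling, 1.87-fold over dendritic cell-like cells. Their myelin sum was 1.18-fold (0.930 to 1.49) that of T cell-like cells and their haemoglobin sum 2.41-fold (0.281 to 9.41) that of monocyte-like cells, both within counting error of no difference.

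**Figure D3:**
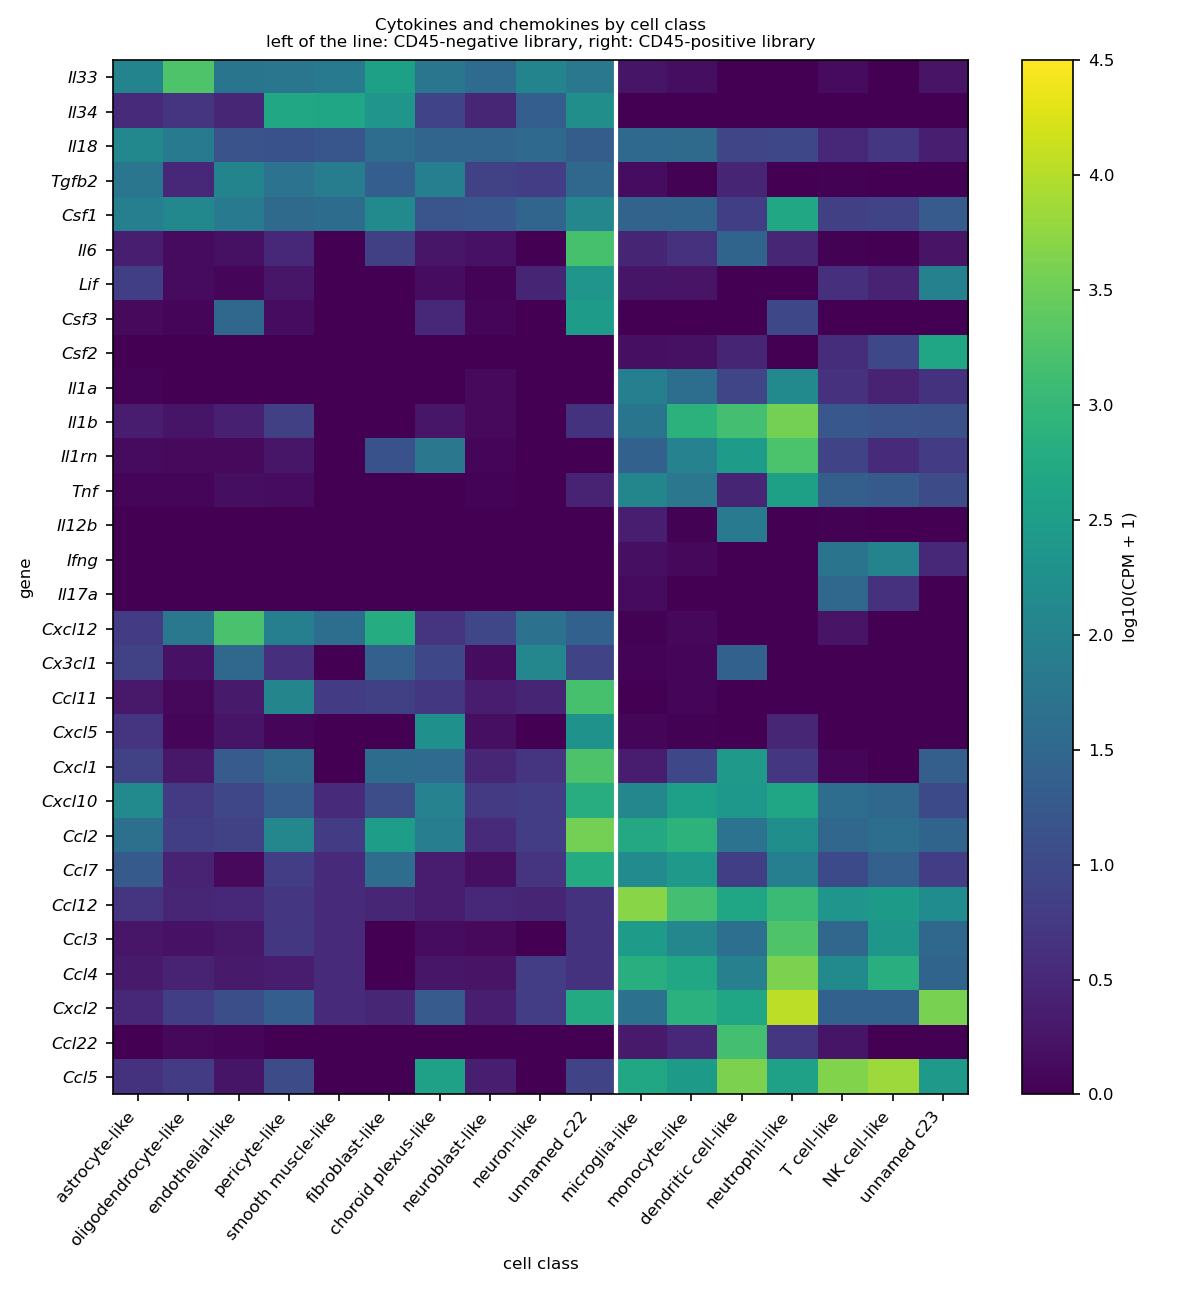
Level of 30 cytokine and chemokine genes (vertical axis) in 10 CD45-negative and 7 CD45-positive groups of cells (horizontal axis), as a heatmap of log10(CPM + 1). The highest value is Cxcl2 in neutrophil-like cells at 11250.1 CPM, and Cxcl12 peaks in endothelial-like cells at 1646 CPM and Il33 in oligodendrocyte-like cells at 1857 CPM.

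**Figure D4:**
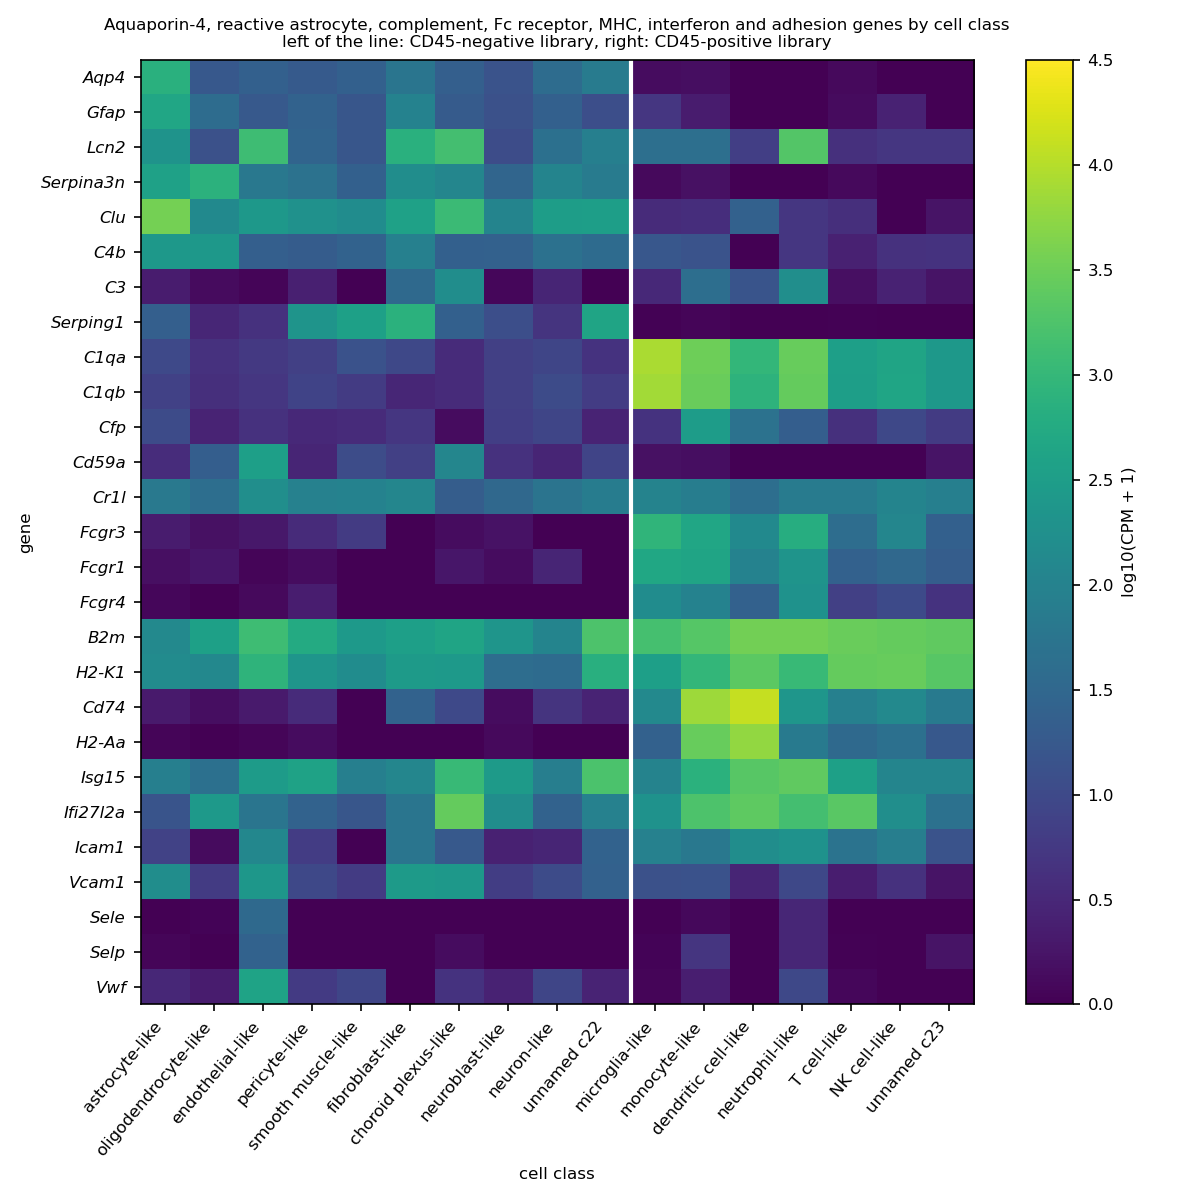
Level of 27 genes of the target antigen, astrocyte reaction, complement, Fc receptors, MHC, interferon response and adhesion (vertical axis) in the same groups of cells (horizontal axis), as a heatmap of log10(CPM + 1). C1qa stands at 8335 CPM in microglia-like cells, Clu at 3613 CPM in astrocyte-like cells and Cd59a at 344 CPM in endothelial-like cells.

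Cells of the same class on both sides of the gate were to be compared for classes with at least 100 cells in each library, and no class reached that number. With the minimum lowered to 50 after seeing the data, astrocyte-like (5223 CD45-negative and 69 CD45-positive cells) and microglia-like cells (85 and 3032) could be compared. Astrocyte-like cells of the CD45-positive library were higher for lists of microglia and leukocyte genes, and microglia-like cells of the CD45-negative library for end-foot, myelin and chemokine genes. RNA carried over from other cells of each library was not separated from expression in these cells.

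In astrocyte-like cells the median log2 ratio of CD45-positive over CD45-negative CPM was 5.58 for Fc receptors, 5.33 for MHC class II, 4.21 for integrins and 3.39 for homeostatic microglia genes. Chemokines (2.19), cell cycle genes (2.19), complement components (1.59), chemokine receptors (1.51), mature neutrophil genes (1.31) and inflammasome genes (1.05) also had positive medians. A gene with 0 UMIs in the 69 cells was set at 9.90 CPM, which lifts the ratios of low genes, so the medians are read by their percentile among matched lists. Of the lists named so far it was 94.95 for chemokine receptors and at least 99.35 for the others, and it was 2.18 for haemoglobin genes, whose median was 2.10. Tmem119, a microglia gene, was at 42.9 against 1.21 CPM and Ptprc at 52.8 against 0.863 CPM. In the 69 cells Tmem119 stood at 6.06%, C1qa at 5.94% and Cx3cr1 at 4.26% of their microglia-like level. NK cell-like cells of the same library were close, at 5.43%, 4.99% and 3.99%, so these levels may be RNA of other cells. The reactive astrocyte list had a median of 0.65 at the 100th percentile, against 0.15 for all genes. The mix of clusters differed. The cluster led by Ptx3, Tgm1 and Gfap held 17.4% of the CD45-positive and 10.8% of the CD45-negative astrocyte-like cells (12 and 562 cells), and a low-UMI cluster led by Aldoc 20.3% and 12.3%, and the ratios do not separate this mix from a difference within cells. Hspb1 was at 574 against 111 CPM (log2 2.37, 2.15 to 2.59), Ccl2 at 201 against 44.7 CPM, Lcn2 at 700 against 206 CPM (log2 1.76, 1.56 to 1.96), Crym at 343 against 93.7 CPM and Fabp7 at 280 against 84.5 CPM. Gfap, at 475 against 454 CPM, and Aqp4, at 640 against 714 CPM, differed by less than counting error. On the CD45-negative side Neat1, a nuclear RNA, was at 1657 against 383 CPM, the glucocorticoid-induced gene Fkbp5 at 160 against 42.9 CPM, Angptl4 at 81.1 against 16.5 CPM and the interferon-inducible GTPase gene Gbp2 at 86.0 against 23.1 CPM. Iigp1, another interferon-inducible GTPase gene, had 1455 UMIs in the CD45-negative and 0 in the CD45-positive cells (log2 of at most -2.34 against a floor of 3 UMIs).

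The other medians in astrocyte-like cells lay closer to 0 or below it. They were 0.73 for adhesion molecules, 0.53 for early activation, 0.43 for MHC class I, 0.38 for hypoxia and glycolysis, 0.33 for damage-associated microglia genes, 0.25 for cytokines and 0.08 for lipid handling. They were -0.09 for blood-brain barrier genes, -0.31 for end-foot genes, -0.33 for interferon-stimulated genes, -0.66 for complement regulators and -2.55 for myelin genes. Adhesion molecules were at the 49.5th, lipid handling at the 50.9th, cytokines at the 28.4th and complement regulators at the 12.6th percentile of matched lists.

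By number of cells, microglia-like cells of the 2 libraries came mainly from different clusters. The cluster led by Saa3 and Ccl12 held 54 of the 85 CD45-negative cells, at a median of 787.5 UMIs, and the cluster led by Gpr34 and P2ry12 held 1702 of the 3032 CD45-positive cells. The Gpr34 and P2ry12 cluster also held 23 CD45-negative cells, at a median of 13496 UMIs. A cluster led by Tnf, Ccl4 and Atf3 held 8, at a median of 19267 UMIs. UMIs were summed, so these deeper cells weigh more in the ratios than their number. Of the lists, MHC class II (0.82) and homeostatic microglia genes (0.43) were higher in the CD45-positive cells, against -0.08 for all genes. Chemokines (-0.84), interferon-stimulated genes (-0.74), cytokines (-0.66), early activation genes (-0.51) and damage-associated microglia genes (-0.34) were lower. Cxcl2 was at 46.8 against 246 CPM (log2 -2.39, -2.64 to -2.14), the scavenger receptor gene Marco at 93.9 against 453 CPM, Hspa1a at 81.7 against 356 CPM, Ccl7 at 146 against 475 CPM and Saa3 at 658 against 1539 CPM. Cxcl13, a B cell attractant, had 1134 UMIs in the CD45-positive and 1 in the CD45-negative cells (log2 4.25, 1.77 to 9.56). Crybb1 was at 165 against 75.8 CPM and Nav3 at 286 against 138 CPM. RNA of other cells moved with the same contrast, with end-foot genes at -6.95, neutrophil granule genes at -6.56, myelin genes at -5.44 and reactive astrocyte genes at -1.93. Complement components had a median of -0.64, which turned positive under 4 alternatives, at 0.12 with at least 100 UMIs per gene and 0.28 with each cell's CPM averaged among them.

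The other medians in microglia-like cells were -0.80 for blood-brain barrier genes, -0.79 for lipid handling, -0.72 for chemokine receptors, -0.55 for adhesion molecules, -0.54 for complement regulators and -0.43 for mature neutrophil genes. They were -0.29 for MHC class I, -0.18 for integrins, -0.12 for hypoxia and glycolysis, -0.06 for inflammasome genes, 0.01 for Fc receptors and 0.02 for cell cycle genes. A gene with 0 UMIs in the 85 CD45-negative cells was set at 5.06 CPM. Chemokine receptors were at the 54.5th, inflammasome genes at the 53.1st, cell cycle genes at the 72.4th, integrins at the 34.2nd, complement regulators at the 29.0th and Fc receptors at the 25.1st percentile of matched lists.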

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

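The tests of random doublets, of free RNA and of shallow sampling were chosen only after the result was seen, while those of a shared droplet, of lost cytoplasm and of dissociation were written beforehand. No biological explanation was tested, since the design has no group that would set these cells apart.

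Cells with both neutrophil and microglia markers made up 3.31% (2.94 to 3.71) of the CD45-positive library, 279 cells that lay in clusters outside the class comparisons and above the 0.0437% that a count of 0 allows. Random droplet doublets of the 2 classes are argued against, since 8.46 were expected, 33.0-fold fewer than seen. Free microglia RNA could not be judged from the microglia share, since high microglia marker scores were part of why these clusters were left unnamed. The median share of microglia markers was 98.7% of that in microglia-like cells, where T cell-like cells had 4.00%. The median share of neutrophil markers was 0.157%, against 0.703% in neutrophil-like and 0.00618% in microglia-like cells. A microglia and a neutrophil held in the same droplet, as a pair that stayed attached might be, stays open: of 1716 genes at 100 CPM or more, 0.0583% lay over 2-fold above both classes, the only such gene being H2-Ab1 at 2.00-fold. The undiluted microglia share, and a median of 23419 UMIs that is 1.90 times the sum of both class medians, are not what an average pair would give.

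Low-UMI cells with microglia markers were 10.1% (9.48 to 10.8) of the CD45-positive library, 853 cells outside the class comparisons with a median of 1409 UMIs, above the share that a count of 0 allows. Shallow sampling of microglia-like cells was not decided, since 2.16% of 2312 genes differed 4-fold or more, between the limits set for either answer. Nuclei, or cells that lost their cytoplasm, may account for them: ribosomal protein genes stood at 0.423 times their level in microglia-like cells, and Malat1, a nuclear RNA, at 5.02 times. Both explanations remain open.

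In the CD45-negative library 173 low-UMI cells with pericyte markers, outside the class comparisons, held Il6 at 1554 CPM (1452 to 1662), where 3 counts would be 5.43 CPM. Their median was 1117 UMIs, and the summed level weighs deeper cells more. With the stricter cell filter an Il6-led cluster of 114 CD45-negative cells had a median of 3338.5 UMIs and was named pericyte-like. The low depth and the missing name thus depend on the filter. Free RNA was not decided, since of 1734 genes at 100 CPM or more, 34 (1.96%) lay over 2-fold above every other cluster of at least 50 cells in that library, between the limits of 1% and 5% set for either answer. Il6 itself reached at most 6.84 CPM in the 27 other clusters. As a leading gene of this cluster, it does not decide the question for the whole profile. Shallow sampling of pericyte-like cells is argued against, since 8.57% of 2276 genes differed 4-fold or more. An early response to tissue dissociation cannot be told apart from a state present in the brain, since the 20 early activation genes stood at a median of 1.77 times their pericyte-like level, between the limits of 1.5 and 2 set beforehand.

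A cluster of 175 CD45-positive cells outside the class comparisons held Csf2 at 458 CPM (424 to 495), where 3 counts would be 2.12 CPM and NK cell-like cells had 8.37 CPM.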

How the results depend on the processing

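Chosen only after the results were seen were the tests with no cluster split, with high-UMI or unnamed clusters named, with microglia-marker-rich cells left out and with classes of at least 50 cells. No paired analysis was possible because each group has 1 library. In all, 121 results were recomputed in 621 alternative values. Of the values of the main results, 69 stayed within their counting interval, 59 moved beyond it and 0 reversed. Of the others 279 stayed, 204 moved and 10 reversed. Only log2 ratios could reverse, since medians per cell and shares of cells, which are many of these values, have no sign. Naming high-UMI clusters moved 0 of 19 values. The free RNA alternative applies within a class only. Where no reason is given, the cause was not tested. With 1 library per group, depth limits only counting error, and the spread between animals is unknown.

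Without a cell filter the CD45-negative medians were 5071 UMIs (5412 in the report) and 2159.5 genes (2259), and thinning gave 630 genes, against 621 in the CD45-positive library (2088). The Ptprc log2 ratio was 6.41 with doublets kept (6.28). The share of CD45-negative cells with a Ptprc UMI was 0.511% thinned (1.09%), and of CD45-positive cells 88.0% with the stricter filter and 47.5% thinned (85.8%), where fewer UMIs per cell lower a share by construction.

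Without a cell filter astrocyte-like cells were 37.8% (40.8%), endothelial-like 10.5% (11.1%), oligodendrocyte-like 20.9% (21.8%), T cell-like 33.1% (30.9%) and CD45-positive immune classes 85.3% (82.7%). The stricter filter gave oligodendrocyte-like 20.8%, T cell-like 31.9% and immune 84.3%. Doublets kept gave astrocyte-like 38.7%, T cell-like 32.9% and immune 84.2%. Leiden resolution 0.5 gave T cell-like 32.9% and immune 85.3%. In each of these settings a T cell-like cluster was led by Calca, Il1rl1 and Gata3, which also led the 175 cells left without a name. It held 268, 245, 263 and 259 CD45-positive cells in the order given, so these T cell-like and immune shares count cells like those 175. Resolution 2 gave microglia-like 34.3% (36.0%), CD45-positive immune 80.4% and CD45-negative immune 0.811% (1.15%). Clustering each library alone gave oligodendrocyte-like 19.9%, microglia-like 24.6% and CD45-positive immune 73.2%. Immune classes came to 86.0% with no cluster split and 98.2% with unnamed clusters counted by their best class.

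Under the median of ratios, TMM and each cell's CPM averaged, the whole-library medians were 2.71, 2.87 and 2.91 for chemokines (2.40), 2.38, 2.53 and 1.40 for complement components (2.06), 7.68, 7.83 and 7.47 for MHC class II (7.36), and -6.13, -5.98 and -5.63 for end-foot genes (-6.45). The scalings shift every list alike.

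Between classes, log2 ratios with each cell's CPM averaged, doublets kept, resolution 2 and microglia-marker-rich cells left out were as follows. Chemokines of neutrophil-like over NK cell-like cells (1.28) were at 1.48, 1.17, 0.90 and 1.502. Cytokines of neutrophil-like over dendritic cell-like cells (1.78) were at 2.02, 1.90, 1.99 and 1.90. Complement components of microglia-like over monocyte-like cells (1.23) were at 1.71, 1.27, 0.72 and 3.11. MHC class II of dendritic cell-like over monocyte-like cells (0.73) was at 0.45, 0.49, 1.96 and 0.26. With doublets kept, interferon-stimulated genes of choroid plexus epithelial-like over endothelial-like cells (1.99) were at 2.18, and adhesion molecules of endothelial-like over fibroblast-like cells (1.39) at 1.22.

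These turned sign. Complement components between microglia-like cells of both libraries (-0.64) were at 0.12 with at least 100 UMIs, 0.28 with each cell's CPM averaged, 0.0550 with the stricter filter and 0.13 with genes under 20% of the highest class left out. MHC class I of dendritic cell-like over T cell-like cells (0.34) was at -0.37 and haemoglobin of neuroblast-like over pericyte-like cells (2.77) at -2.57 at resolution 2. With each cell's CPM averaged, homeostatic microglia genes of neuron-like over smooth muscle-like cells (0.25) were at -0.57, reactive astrocyte genes of endothelial-like over fibroblast-like cells (0.20) at -0.0476, and hypoxia and glycolysis of monocyte-like over microglia-like cells (0.04) at -0.0442, or -0.0600 without microglia-marker-rich cells.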

Other observations

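The values in this part were picked by cluster after their results were seen, and all tests named here were chosen at that point. They describe clusters within classes, and genes that define a cluster are given as its description. Among astrocyte-like cells of the CD45-negative library, a cluster of 562 cells (4.38%) stood apart in the reactive astrocyte genes, which summed to 9637 CPM (9529 to 9746), against 968 CPM in the main cluster of 2041 cells. Gfap was at 1686 against 333 CPM, Lcn2 at 1545 against 35.7 CPM, Ptx3, a secreted pattern recognition protein gene, at 618 against 3.60 CPM, and Cxcl10 at 988 against 21.99 CPM. In the same clusters interferon-stimulated genes summed to 2916 against 460 CPM, and aquaporin-4 and astrocyte end-foot genes to 2712 against 4550 CPM. Aqp4, a marker left out of that sum, was at 746 CPM (716 to 777) against 618 CPM (605 to 632). Over all astrocyte-like cells of the library Aqp4 was at 714 CPM, so the cluster of 562 cells lay close to the class level. A further astrocyte-like cluster of 1978 cells, nearly as large as the main one, is not part of these contrasts. Among oligodendrocyte-like cells, a cluster of 699 cells held Il33 at 3211 CPM (3172 to 3250) with Mbp at 1092 CPM, and a cluster of 1494 cells held Il33 at 1330 CPM with Mbp at 3976 CPM. A group of 54 cells without a name, with Fabp7, Egfr and Dll1 among its leading genes, held the cycling genes Hmgb2 at 2011 CPM and Mki67 at 160 CPM.

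On the CD45-positive side, a microglia-like cluster of 351 cells held Tnf at 616 CPM, Ccl4 at 3178 CPM and Fos at 850 CPM, against 28.6, 214 and 31.8 CPM in the main cluster of 1702 cells. Another of 979 cells held Saa3 at 1374 CPM and P2ry12 at 137 CPM, against 404 and 499 CPM in the main cluster. In the cluster of 351 cells Atf3, Egr1 and Zfp36, early activation genes like Fos, were among the leading genes. An early response to tissue dissociation was not tested for that cluster. T cell-like cells fell into a cluster of 1832 cells with Cd4 at 226 CPM and Foxp3 at 27.6 CPM, a cluster of 648 cells with Cd8a at 711 CPM and Gzmb at 1679 CPM, a cluster of 41 cells led by cell cycle genes such as Mki67 and Birc5, and a cluster of 82 cells led by Trdc, a gamma-delta T cell receptor gene, with Il17a at 552 CPM (493 to 616). The 175 cells without a name that carried Csf2 held Gata3 at 778 CPM (733 to 825), Il1rl1, the receptor of Il33, at 693 CPM (651 to 738) and Il5 at 47.97 CPM. The T cell genes Trac and Cd3e were at 4.23 and 2.82 CPM in them, and Ptprc at 428 CPM. The 3 cells that held most immunoglobulin UMIs also held 96.0% of Jchain and 78.3% of Mzb1, genes of antibody-secreting cells.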
